A study of Mus musculus with 2 samples.

How the data were processed

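Nuclei of spinal cord were profiled in 2 libraries, PBS and AEVs, each a pool of 3 mice killed on day 7 after a T10 contusion made with a rod of 5 g and 1 mm diameter dropped from 6 cm. Each injection held 100 µL, with 100 µg of vesicle protein in the AEVs group. Per the labels' protocols, nuclei came from cord frozen in liquid nitrogen, and libraries were made with a SeekGene droplet kit that reads the 3-prime end of polyadenylated RNA. The deposited values are raw UMI counts per gene and barcode, whole numbers with no scaling, and the lowest total per barcode is 500 UMIs in both libraries as deposited, with no shallower barcode in them. The genome build mm10 and the use of Seurat are stated in the submitters' processing notes, with no version. The aligner, the annotation, and any removal of ambient RNA or doublets by the authors are not given in the sources used here. Gene symbols and identifiers were taken from the files, 32158 of 32285 identifiers were found in GENCODE release M21 of that build, and coordinates come from that annotation.

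Nuclei were kept with at least 300 detected genes, at least 500 UMIs and under 5% of UMIs from mitochondrially encoded genes. In the PBS library 5 barcodes had under 300 genes and 527 had 5% or more mitochondrial UMIs, against 4 and 103 in the AEVs library. Doublets were called per library with Scrublet in scanpy 1.11.5, at score thresholds of 0.145 and 0.141, and 1001 PBS and 1390 AEVs nuclei were removed, 6.77% and 8.20% of those that had passed. The kept nuclei held 70213111 and 68183360 UMIs. Both libraries were clustered together, with UMIs scaled to 10000 per nucleus and log-transformed, 2000 variable genes chosen within each library and merged, 30 principal components, 20 neighbours and the Leiden method at resolution 1 (igraph 0.11.9, leidenalg 0.10.2). No batch integration was applied, because library and treatment coincide.

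The 31 clusters were named by fixed marker genes of 17 classes. A cluster took the class with the largest share of markers raised at least 2-fold over the median cluster. At least 3 such markers were needed, and no other class could have more markers among the 10 leading genes. A cluster whose median UMIs were under 1/3 of those of its library, with no marker of its best class among the leading genes, stayed unnamed. Classes carry the ending -like, since they rest on RNA alone. Clusters 4 and 30, in which Gpnmb led, were set apart by a rule made after their genes were seen. Cluster 4 had 8 microglia and 7 macrophage markers raised, and cluster 30, of 57 nuclei, 8 of 10 oligodendrocyte and 6 microglia markers. The scoring used to name clusters was made after the data were seen too. Because named genes could shape the clusters, nuclei were also clustered again without the 463 variable genes that were named, listed or leading.

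UMIs were summed per class and library and divided by the class total. Levels carry exact Poisson intervals, ratios exact conditional binomial intervals and shares exact Clopper-Pearson intervals, all at 95% and for counting error only, which leaves out differences between mice, pools and collections. No test across samples was possible with 1 library per group, so no p-value, standard error or number of changed genes is given. Values are given for classes with at least 100 nuclei in each library at the settings above, and for all nuclei. Alternatives left fewer in some, with 87 PBS nuclei in the Schwann-like class when doublet calls were kept, and 97 Schwann-like and 85 macrophage-like AEVs nuclei after thinning. The named genes of a class are the 5 with the highest and the 5 with the lowest ratio, and for all nuclei the 10 of each, among genes with at least 50 UMIs in the library where they are higher, found in at least 2% of its nuclei, and with a pooled level in the class of at least 0.25 of that in the class where the gene is highest, a condition against free RNA. Mitochondrial, ribosomal protein and hemoglobin genes and predicted genes without a symbol were left out. For each gene list described, the 2 members with the highest and the 2 with the lowest ratio could be named too. A ratio with 0 UMIs in a library is a bound against 3 counts, and with 1 to 3 UMIs it is given with its interval.

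For 31 gene lists, the median log2 ratio was taken over members with at least 20 UMIs in both libraries together, with a 95% interval from 500 Poisson redraws and a percentile among 10000 random lists of the same size drawn from the 50 genes nearest in level to each member. The symbols Aldoa, Cap23, Clec7a, Ctgf, Ddit3 and Mx1 matched nothing in the files. Filters, clustering settings, marker genes, lists and the rule for named genes were chosen before the data were examined. Which of the resulting values lead the text was chosen after they were seen. Further lists were added after the values were seen, for clock genes of the evening and of the morning phase, glucocorticoid-responsive, cold-inducible, heat shock and immediate early genes.

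The steps were tested on simulated Poisson counts drawn from the PBS means at the real totals, with 200 genes changed 2-fold or 4-fold. All changed genes took the right direction at both sizes in each simulation (all, oligodendrocyte-like, microglia-like and macrophage-like nuclei). The intervals held the true value for 95.4% of 17297 genes over all nuclei and 95.8% of 1106 genes in macrophage-like nuclei. The intervals assume the same Poisson model, so this coverage follows from the simulation. It does not cover UMIs of a gene that lie in a few nuclei. Of 100 unchanged lists, 5 over all nuclei and 7 in oligodendrocyte-like nuclei lay outside the middle 95% of random lists. The alternatives were a stricter nucleus filter of 800 genes and 1000 UMIs, no mitochondrial limit, doublet calls kept, Leiden resolutions of 0.5 and 2, genes scaled within each library, TMM factors from edgeR 4.0.16, median-of-ratios size factors from DESeq2 1.42.0, a mean over nuclei, nuclei thinned to 1000 UMIs, and other limits on list members. A same mix of clusters in both libraries and the second clustering were added after the data were seen, as were some pairings of lists with alternatives and values of oligodendrocyte precursor-like nuclei at resolution 2. The markers of the classes were measured as lists in the same way. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and in R 4.3.3. Gene values of T or NK cell-like, ependymal-like, mural-like and unnamed nuclei are not analysed here, because a library held under 100 of them or no class was given.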

Results

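Single-nucleus RNA was measured in injured spinal cord of C57BL/6 mice 7 days after a contusion at T10, a thoracic level. Mice received tail-vein injections on 5 days of either athlete-derived extracellular vesicles (AEVs, membrane particles shed by cells) or the carrier, phosphate-buffered saline (PBS). Nuclei of 3 mice were pooled into 1 library per group, so each group has 1 value and no difference between the libraries has a replicate check. The PBS library held 15325 barcodes with 82953601 unique molecular identifiers (UMIs), and the AEVs library held 17055 barcodes with 81875882 UMIs. After removal of poor nuclei and doublets, 13793 PBS and 15559 AEVs nuclei remained, with medians of 2587 and 2403 UMIs and of 1452 and 1415 detected genes. Levels are counts per 1000000 UMIs of the class (CPM), ratios are AEVs over PBS, and a pair of values is given with PBS first. Ranges in parentheses are 95% intervals that cover counting error only.

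The comparison asks how the injured cord of vesicle-treated mice differed from that of carrier-treated mice, first in its mix of cell classes. Fibroblast-like nuclei, a class that includes cells of the fibrotic scar, made up a smaller part of the AEVs library. They held 3.49% (3.21 to 3.79) against 6.79% (6.38 to 7.23) of the PBS library, a share ratio of 0.514 (0.461 to 0.572). The lower share lay in cluster 8, led by Col1a1, with 725 PBS and 294 AEVs nuclei. Cluster 18 of the same class, led by Slc7a11, held 212 PBS and 249 AEVs nuclei. T or NK cell-like nuclei, the infiltrating lymphocytes, numbered 28 in the AEVs library and 136 in the PBS library, for a share ratio of 0.183 (0.117 to 0.276). Neuron-like nuclei held a larger share, 31.3% (30.5 to 32.0) against 26.5% (25.8 to 27.2), and oligodendrocyte-like nuclei, the myelin-forming class, held 35.5% (34.7 to 36.2) against 33.0% (32.2 to 33.8). The share of microglia-like nuclei, the resident immune cells of the cord, was similar in both libraries at the main settings, with a ratio of 1.02 (0.940 to 1.12). It was higher in the AEVs library with the stricter nucleus filter, 1.23 (1.13 to 1.35), with no mitochondrial limit, 1.17 (1.07 to 1.27), and at Leiden resolution 2, 1.10 (1.01 to 1.20).

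A myeloid group led by Gpnmb, a transmembrane glycoprotein of phagocytes loaded with lipid, was held apart from both microglia-like and macrophage-like nuclei and made up 7.34% (6.91 to 7.78) of the PBS and 5.74% (5.38 to 6.12) of the AEVs library. Share ratios were 0.646 (0.505 to 0.824) for macrophage-like nuclei, 0.772 (0.671 to 0.887) for oligodendrocyte precursor-like nuclei, 1.11 (1.01 to 1.21) for astrocyte-like nuclei and 1.31 (1.10 to 1.55) for endothelial-like nuclei. Schwann-like nuclei, from the myelinating cells of peripheral nerve, had a ratio of 1.02 (0.817 to 1.28), or 0.751 with the stricter nucleus filter, ependymal-like nuclei 0.961 (0.705 to 1.31) and mural-like nuclei, the pericytes and smooth muscle of vessels, 1.31 (0.912 to 1.90). Cluster 12, with a median of 772.5 UMIs, was left unnamed and held 3.39% (3.10 to 3.71) of the PBS and 1.53% (1.34 to 1.74) of the AEVs nuclei. It had 8 of 10 neuron markers raised, though none among its 10 leading genes, and its nuclei are not in the neuron-like share. When nuclei were clustered again without the genes that the comparison names, the ratios were 0.540 for fibroblast-like, 0.198 for T or NK cell-like, 1.21 for neuron-like and 0.724 for Gpnmb-led myeloid nuclei. That neuron-like share leaves out an unnamed cluster led by Nefh, Nefm and Nefl, with 7 neuron markers raised and 670 PBS and 353 AEVs nuclei. It also leaves out unnamed clusters of 61 and 109 and of 17 and 26 nuclei whose best class was neuron. Dissection and the yield of nuclei can set such shares. Median depth differed between classes, from 1116 UMIs in Schwann-like nuclei of the AEVs library to 9739 UMIs in neuron-like nuclei of the PBS library. Within most classes it was lower in the AEVs library, at 9739 and 7447 UMIs in neuron-like and 2387 and 2011.5 in oligodendrocyte-like nuclei. It was higher there in macrophage-like (1389 and 1497.5) and T or NK cell-like nuclei (1327 and 1641.5).

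**Figure D1:**
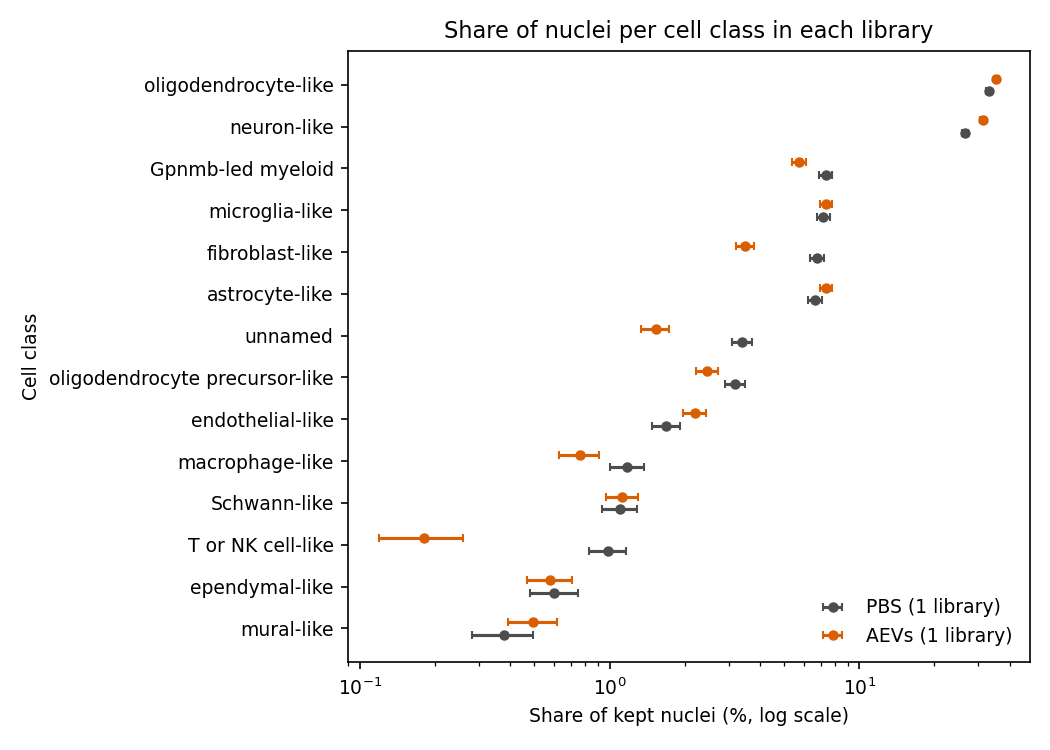
Share of nuclei (percent of kept nuclei, horizontal axis) of each cell class in the PBS and AEVs libraries, 1 library of 3 pooled mice each, with bars for exact 95% binomial intervals. Fibroblast-like nuclei lie at 6.79% in the PBS and 3.49% in the AEVs library, and neuron-like nuclei at 26.5% and 31.3%.

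Over all nuclei, Sult1a1, Apod, Hif3a and Cebpb had the highest ratios of AEVs to PBS among the named genes, and Col1a1, Sfrp4 and H2-Eb1 were among those with the lowest. Apod, which encodes the lipid-binding protein apolipoprotein D, measured 1193 CPM (1185 to 1202) in the PBS and 5384 CPM (5367 to 5401) in the AEVs library, 4.51-fold higher. Cdkn1a, which encodes the cell cycle inhibitor p21, had a log2 ratio of 1.91 (1.84 to 1.99), Cebpb, a transcription factor of acute-phase and inflammatory genes, 2.08 (1.93 to 2.23), and Hif3a, a member of the hypoxia-inducible factor family, 2.09 (1.99 to 2.20). Sult1a1, a phenol sulfotransferase, stood at 2.22 (2.01 to 2.43). The other named genes that were higher were Dcst2 (2.07), Vmn2r1 (1.91), Gabrr2 (1.72), Itgad (1.72) and Ovgp1 (1.71); averaging over nuclei gave 3.01 for Dcst2, and thinning gave 2.58 for Vmn2r1.

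Col1a1, a chain of type I collagen and the main fibre of scar, measured 109.8 CPM (107 to 112) in the PBS and 17.1 CPM (16.2 to 18.1) in the AEVs library, 6.41-fold lower. With both libraries given the same mix of clusters, its log2 ratio was -1.97 instead of -2.68, that of Col3a1, a chain of type III collagen, -1.10 instead of -1.84, and that of Sfrp4, a secreted modulator of Wnt signalling, -2.02 instead of -2.65. H2-Eb1, H2-Aa and H2-Ab1, chains of the class II complexes that present antigen to T cells, had log2 ratios of -2.32 (-2.54 to -2.10), -2.13 (-2.32 to -1.94) and -1.97 (-2.19 to -1.76). Of the antigen presentation list, 7 of 11 measured members were lower, with a median log2 ratio of -0.61 (-0.86 to -0.36). Macrophage markers were lower over all nuclei too for 8 of 10, median -0.47 (-0.55 to -0.30), and dendritic cell markers for 4 of 4, -0.44 (-0.76 to -0.13). H2-D1, a class I heavy chain, stood at 0.39 and Tap1, a subunit of the class I peptide transporter, at 0.17. The matrix list was lower for 14 of 19 members, median -0.40 (-0.45 to -0.29), with Acta2, the smooth muscle actin, at 2.57 (2.27 to 2.89) and Thbs2, a matrix thrombospondin, at 0.41 against that direction. Nr4a3 (-2.12), Ccn1 (-1.76), Loxl1 (-1.81) and Fam180a (-2.20) complete the named genes that were lower, and the same mix of clusters gave -1.59 for Fam180a.

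The key genes of the comparison, given by identifier and position on mm10, are Apod (ENSMUSG00000022548, chromosome 16, 31296192 to 31314808), Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), Hif3a (ENSMUSG00000004328, chromosome 7, 17031507 to 17062427), Cebpb (ENSMUSG00000056501, chromosome 2, 167688915 to 167690418), Sult1a1 (ENSMUSG00000030711, chromosome 7, 126672865 to 126676432), Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) and H2-Eb1 (ENSMUSG00000060586, chromosome 17, 34305867 to 34316674). Named later for single classes are Ifit3 (ENSMUSG00000074896, chromosome 19, 34583531 to 34588731), Hspb1 (ENSMUSG00000004951, chromosome 5, 135887919 to 135889563), Top2a (ENSMUSG00000020914, chromosome 11, 98992943 to 99024189), Cemip2 (ENSMUSG00000024754, chromosome 19, 21778342 to 21858360), Apold1 (ENSMUSG00000090698, chromosome 6, 134981718 to 134986836) and Nr4a3 (ENSMUSG00000028341, chromosome 4, 48045153 to 48086447). All of them are protein-coding in the annotation.

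Oligodendrocyte-like nuclei, the most numerous class, were higher in Cdkn1a, Apod and Hif3a and in a list of injury genes in the AEVs library. Cdkn1a measured 32.5 CPM (29.3 to 35.8) in the PBS and 319 CPM (309.5 to 329) in the AEVs library, 9.84-fold higher, and Apod 4520.1 CPM (4483 to 4558) and 24470.3 CPM (24384 to 24557), 5.41-fold higher. Hif3a was 6.06-fold higher, with a log2 ratio of 2.60 (2.45 to 2.75), and Phyhd1, a member of the phytanoyl-CoA dioxygenase family, had a log2 ratio of 2.54 (2.38 to 2.69). Hif3a was not particular to this class, as it was also among the highest named genes of oligodendrocyte precursor-like and fibroblast-like nuclei. Dcst2, best known as a sperm membrane protein, had 12 and 174 UMIs and a log2 ratio of 3.83 (2.99 to 4.81), against 3.07 after thinning. Of the list for injured or disease-associated oligodendrocytes, 9 of 13 measured members were higher, with a median of 0.74 (0.58 to 0.84) at percentile 100 of the random lists. Trib3, a pseudokinase of the integrated stress response, had 2 and 33 UMIs and a log2 ratio of 4.02 (2.05 to 7.13), while Il33, an alarmin that oligodendrocytes release on injury, was lower at -1.56 (-1.63 to -1.49) and Anxa5, a phospholipid-binding annexin, measured -0.09 (-0.25 to 0.06).

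Lower in the same class were Dcc, the netrin-1 receptor of axon and process guidance, 4.38-fold, and Cryab, a small heat shock protein abundant in mature oligodendrocytes, 3.49-fold. Cacna2d4, a calcium channel subunit, had a log2 ratio of -1.84 (-2.44 to -1.27), March1, a ubiquitin ligase, -1.75 (-1.80 to -1.70), and Ninj2, an adhesion protein of nerve injury, -1.66 (-1.78 to -1.54). The myelin list did not lean to one side, with 8 of 15 members higher and a median of 0.03 that took the other sign under both other scalings. Cldn11, the tight junction protein of myelin, stood at 0.60 and Mal, a myelin proteolipid, at 0.38, against -0.97 for Ugt8a, which makes galactosylceramide. Differentiation genes had a median of -0.05 with 6 of 13 higher, and the apoptosis list had 13 of 16 higher, median 0.24 (0.05 to 0.34), led by Cdkn1a and by Bbc3, the p53 target PUMA, at 2.39 (1.86 to 2.95). These myelin, differentiation and apoptosis medians all lay inside the middle 95% of random lists of genes of like level. Cluster 5 held 4.37% of this class in the PBS and 20.6% in the AEVs library, and cluster 0, the largest, 57.9% and 47.8%. Among markers of other cells in this class, macrophage markers were lower for 5 of 5, median -1.07 (-1.20 to -0.30), and neutrophil markers for 4 of 4, -0.78 (-1.23 to -0.45). Astrocyte markers were lower for 7 of 10, -0.21 (-0.38 to -0.10), while erythroid markers were higher for 5 of 5, 0.94 (0.79 to 1.46). The median log2 ratio of all genes with at least 100 UMIs was 0.12 in this class, and TMM scaling would shift every value in it by -0.13.

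**Figure D2:**
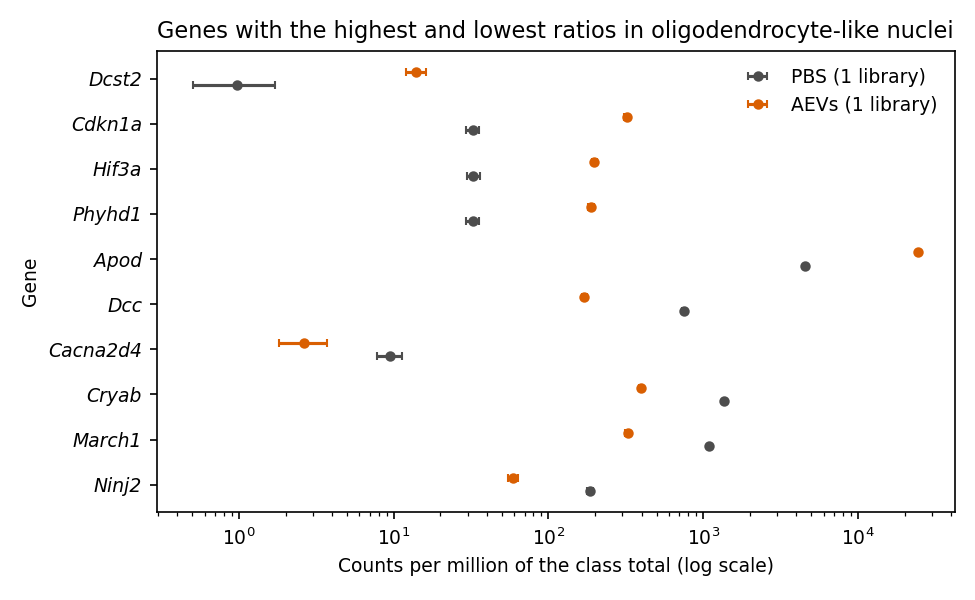
Level (CPM, log axis) of the named genes of oligodendrocyte-like nuclei in the PBS and AEVs libraries, 1 library of 3 pooled mice each, with exact 95% Poisson intervals as bars. Cdkn1a lies at 32.5 and 319 CPM, and Cryab, among the genes that were lower, at 1371 and 393 CPM.

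Oligodendrocyte precursor-like nuclei, the dividing progenitors of that lineage, had fewer cell cycle transcripts in the AEVs library. All 20 measured cell cycle genes were lower, with a median log2 ratio of -2.15 (-2.58 to -1.75) at percentile 0 of the random lists. Members with at least 100 UMIs alone had a median of -1.03. Top2a, the topoisomerase of chromosome segregation, had 114 and 10 UMIs and was 8.23-fold lower, Mki67, the proliferation marker Ki-67, had 80 and 3 UMIs and a log2 ratio of -4.27 (-6.58 to -2.67), and Brip1, a DNA repair helicase, had 30 and 1 UMIs and -4.44 (-9.79 to -1.85). Cenpf, a kinetochore protein, had a log2 ratio of -3.51 (-5.43 to -2.08), and the smallest differences were those of Ezh2, a histone methyltransferase, at -0.69 and Anln, a cytokinesis protein, at -0.94. Averaging over nuclei gave -4.08 for Top2a and -4.67 for Cenpf, for which thinning gave -2.02.

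Over the whole class, genes that mark the step from precursor to myelinating cell were lower in the AEVs library, along with a smaller number of differentiating nuclei. At Leiden resolution 2 the class parted in 2, with 112 PBS and 44 AEVs nuclei named differentiating oligodendrocyte-like, a share ratio of 0.348 (0.240 to 0.498), and 328 and 339 left as precursor-like. Before that split 12 of 14 members of the differentiation list were lower, median -0.67 (-0.74 to -0.48), with the lineage transcription factors Olig2 at 0.31 and Sox10 at 0.19. Of the myelin list 14 of 15 were lower, median -0.61 (-0.84 to -0.49), with Mbp, myelin basic protein, at -1.20 and Mobp at -1.36. In the nuclei left as precursor-like the differentiation median was -0.06 (-0.22 to 0.03), and the myelin median turned to 0.51 (0.31 to 0.77) with 13 of 15 higher. The cell cycle median was -2.61 (-3.05 to -2.19) there, all 20 members lower. Cemip2, a hyaluronan-degrading membrane enzyme, had 382 and 21 UMIs in the whole class and a log2 ratio of -3.72 (-4.42 to -3.08), against -2.36 after thinning, -2.70 averaged over nuclei and -0.61 in the nuclei left as precursor-like. Enpp6, a choline phosphodiesterase of newly forming oligodendrocytes, had a log2 ratio of -1.42 (-1.70 to -1.16) in the whole class. Among cell type markers in the whole class, 10 of 10 of oligodendrocytes were lower, median -0.98 (-1.22 to -0.86), as were 6 of 6 of differentiating ones, median -0.77 (-0.95 to -0.66), while those of neurons and astrocytes had medians of 0.55 and 0.47.

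The precursor programme of the whole class had a median of 0.18 (0.12 to 0.22), inside the middle 95% of random lists, with Pdgfra, the growth factor receptor that defines these cells, at 0.35, Olig1 at 0.32 and the matrix protein Tnr at -0.35. In the nuclei left as precursor-like at resolution 2 that median was 0.01 (-0.10 to 0.02), and the median of oligodendrocyte precursor markers was -0.33 (-0.37 to -0.25). Higher in the AEVs library were Hif3a at 2.49 (2.03 to 2.98) and the interferon-inducible Rtp4, Ddx60 and Ifit3 at 2.44 (1.85 to 3.09), 2.09 (1.74 to 2.44) and 1.95 (1.39 to 2.53); thinning gave 3.42 for Rtp4 and 1.48 for Ddx60. Of the injured-oligodendrocyte list 6 of 9 members were higher, median 0.48 (0.28 to 0.69), with Cdkn1a at 1.97 and Klk6, a serine protease, at -1.12.

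Interferon response genes, the antiviral and inflammatory targets of type I interferon, were higher in the AEVs library in microglia-like, Gpnmb-led myeloid, oligodendrocyte precursor-like and astrocyte-like nuclei. In microglia-like nuclei 15 of 15 measured members were higher, with a median log2 ratio of 1.25 (1.04 to 1.42), in Gpnmb-led myeloid nuclei 15 of 15, median 1.04 (0.83 to 1.27), in oligodendrocyte precursor-like nuclei 15 of 15, median 0.98 (0.63 to 1.32), and in astrocyte-like nuclei 15 of 15, median 0.57 (0.33 to 0.75). Each of these medians lay at percentile 100 of the random lists, a description of these libraries. Members at 0.25 or more of the level of their highest class had a median of 1.62 in Gpnmb-led myeloid nuclei, and those with at least 100 UMIs one of 0.60 in oligodendrocyte precursor-like nuclei. Ifit3, which binds viral RNA complexes, measured 23.5 and 104 CPM in microglia-like nuclei of the PBS and AEVs libraries, and Irf7, the transcription factor that amplifies interferon production, had a log2 ratio of 2.04 (1.36 to 2.78) there. Usp18, which restrains interferon receptor signalling, and Oasl2, an oligoadenylate synthetase-like protein, had log2 ratios of 2.11 (1.62 to 2.63) and 2.04 (1.73 to 2.35) in Gpnmb-led myeloid nuclei. Ddx58, the RNA sensor RIG-I, had a log2 ratio of 0.48 in microglia-like nuclei.

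In other classes the median of the same list lay nearer to 0. Its median was 0.47 (0.27 to 0.56) in oligodendrocyte-like nuclei with 14 of 15 higher, 0.32 (0.19 to 0.45) in neuron-like nuclei with 12 of 15 higher, 0.23 (-0.06 to 0.37) in fibroblast-like nuclei, 0.29 (0.04 to 0.78) in macrophage-like nuclei and 0.18 (0.05 to 0.56) in endothelial-like nuclei. Schwann-like nuclei had 3 of 8 members higher and a median of -0.21 (-0.58 to 0.36), but 0.50 with doublet calls kept. In neuron-like, fibroblast-like, macrophage-like, endothelial-like and Schwann-like nuclei the median lay inside the middle 95% of random lists. Over all nuclei 15 of 15 members were higher, median 0.55 (0.46 to 0.60), with Oasl2 at 1.10 (0.98 to 1.22).

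**Figure D3:**
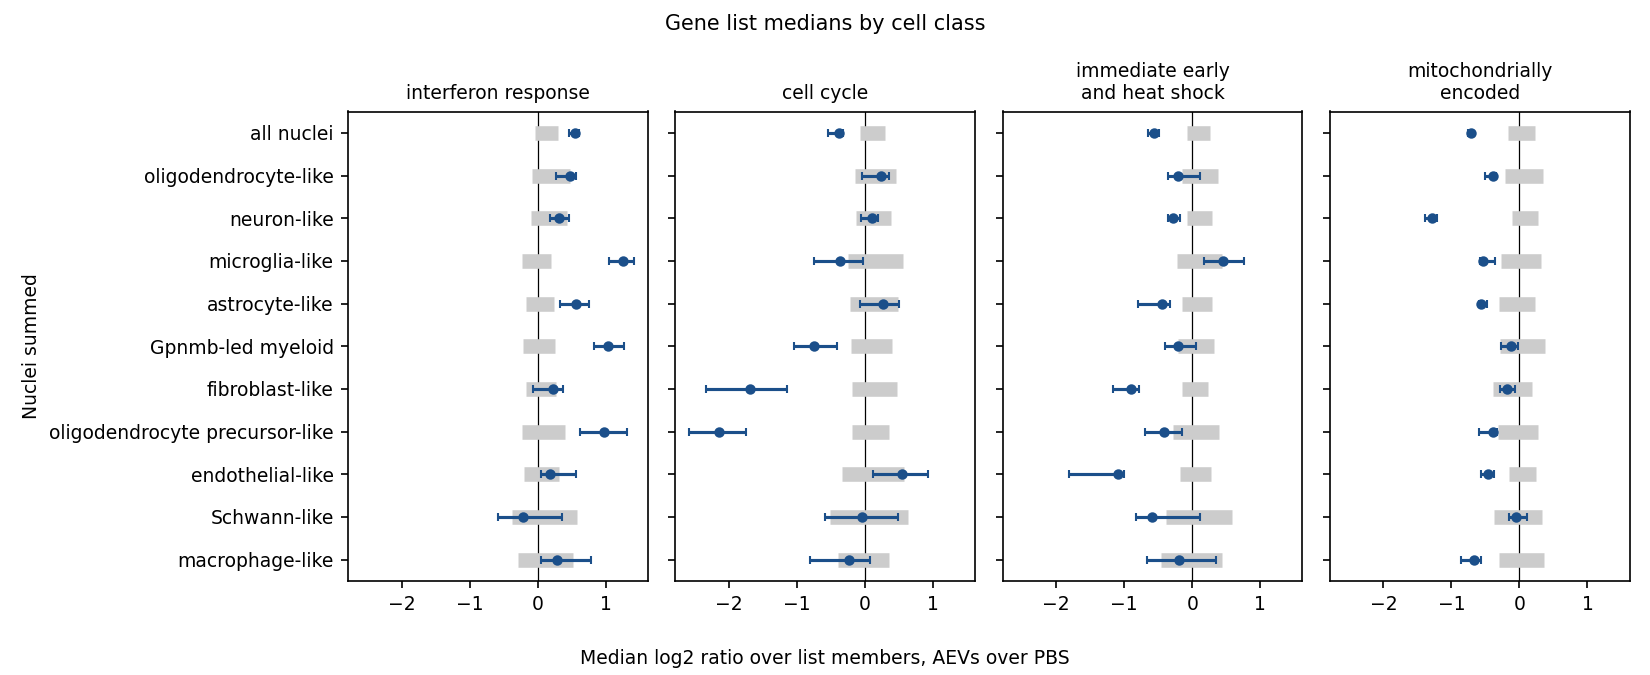
Median log2 ratio (AEVs over PBS, horizontal axis) of 4 gene lists in each class and in all nuclei, from 1 library of 3 pooled mice per group; points are medians, bars their 95% counting intervals, and grey bands the middle 95% of random lists matched on level. The interferon median lies at 1.25 in microglia-like and -0.21 in Schwann-like nuclei, and the cell cycle median at -2.15 in oligodendrocyte precursor-like nuclei.

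Microglia-like nuclei of the AEVs library were higher in Cebpb and in the pro-inflammatory list. Cebpb measured 17.5 CPM (11.7 to 25.1) in the PBS and 152 CPM (134 to 172) in the AEVs library, 8.72-fold higher, Ddit4, an inhibitor of mTORC1, had a log2 ratio of 2.49 (1.98 to 3.04) and Myc, a growth-promoting transcription factor, 2.11 (1.23 to 3.10), or 2.96 after thinning. Of the pro-inflammatory list 11 of 16 members were higher, median 0.40 (0.17 to 0.62), with Tnf at 4 and 24 UMIs and 2.51 (0.97 to 4.499), Nfkbia, the inhibitor of NF-kappaB, at 1.06, and the chemokines Ccl5 and Ccl4 at -1.89 and -0.79. Fcrls, a receptor gene typical of resident microglia, was lower at -1.56 (-1.77 to -1.34), as was Gal3st4, a sulfotransferase, at -1.93 (-2.40 to -1.48). Homeostatic genes otherwise lay near the level of the PBS library, median -0.08 (-0.18 to -0.02), with P2ry13, a purinergic receptor, at 0.46 and the secreted Olfml3 at -1.10. Disease-associated genes had 8 of 18 members higher and a median of -0.07 (-0.24 to 0.12), with Lgals3, galectin-3, at 0.97 and Ch25h, which makes an oxysterol, at -2.92 (-4.63 to -1.57). Complement genes had 6 of 10 higher, median 0.22 (0.07 to 0.36). Antigen presentation genes had 6 of 8 higher, median 0.29 (0.13 to 0.36). The homeostatic, disease-associated, complement and antigen presentation medians lay inside the middle 95% of random lists, and the pro-inflammatory median at percentile 99.2. Oligodendrocyte markers were lower for 8 of 10 in these nuclei, median -0.33 (-0.49 to -0.14).

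Gpnmb-led myeloid nuclei shared the interferon difference and had few class II transcripts in the AEVs library. H2-Aa had 153 and 5 UMIs and a log2 ratio of -4.59 (-6.23 to -3.33), H2-Eb1 83 and 1 UMIs and -6.03 (-11.35 to -3.51), while the whole list had a median of -0.09 (-0.40 to 0.14), inside the middle 95% of random lists. Dkk2, a Wnt antagonist, was lower at -2.72 (-3.31 to -2.17), Wee1, a kinase that delays mitosis, at -3.02 (-4.52 to -1.82) or -3.66 after thinning, and Cd5l, a secreted scavenger receptor protein of macrophages, at -2.36 (-3.56 to -1.34). Gpx3, a secreted glutathione peroxidase, was higher at 2.20 (1.69 to 2.72). Of the disease-associated list 13 of 19 members were higher, median 0.40 (0.20 to 0.43), with Spp1, osteopontin, at 0.53 and Ctsb, a lysosomal protease, at 0.57. The cell cycle list had 13 of 16 lower, median -0.75 (-1.04 to -0.41). Along with these, macrophage markers were lower for 6 of 8, median -0.78 (-0.88 to -0.50) at percentile 0, and microglia markers higher for 7 of 8, median 0.47 (0.36 to 0.67) at percentile 99.5. Fibroblast markers had a median of -2.86 (-3.66 to -2.05) and oligodendrocyte markers -0.60 (-0.82 to -0.41). Oligodendrocyte precursor markers were lower for 6 of 6, median -1.01 (-1.55 to -0.72), and differentiating oligodendrocyte markers for 4 of 4, -1.10 (-1.44 to -0.78).

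Macrophage-like nuclei, 162 in the PBS and 118 in the AEVs library, were higher in complement and disease-associated genes. All 9 measured complement genes were higher, median 0.86 (0.77 to 1.22), with the receptor C3ar1 at 2.07 (1.19 to 3.04) and C1qc, a chain of C1q, at 1.27 (1.05 to 1.49), and 11 of 13 disease-associated genes were higher, median 0.80 (0.54 to 1.05), with Spp1 at 2.40 (1.83 to 3.02) and the lipid receptor Trem2 at 1.63 (0.98 to 2.32). Alternative activation genes had 6 of 8 higher, median 0.85 (0.36 to 1.10), with the scavenger receptor Msr1 at 1.33 and the chitinase-like Chil3 at 1.29. Lipid and lysosome genes had 11 of 16 higher, median 0.33 (0.08 to 0.62), with the protease Ctsl at 2.27 (1.57 to 3.04). Saa3, an acute-phase protein, had 9 and 83 UMIs and a log2 ratio of 3.50 (2.503 to 4.68), or 2.46 after thinning and 2.86 averaged over nuclei. Over whole libraries 5 nuclei held 171 of the 436 Saa3 UMIs of PBS and 100 of the 204 of AEVs. Of the antigen presentation genes 7 of 10 were lower, median -0.77 (-0.94 to -0.61), with H2-Ab1 at -2.20 (-2.52 to -1.89) and Tap1 at 1.21. Markers of other cells differed in this class as well. Both measured dendritic cell markers, Cd209a and Flt3, were lower, median -3.85 (-4.10 to -2.70), while 4 of 4 erythroid, 4 of 4 astrocyte and 2 of 2 Schwann markers were higher, with medians of 4.60 (4.37 to 4.94), 1.40 (0.61 to 2.06) and 2.99 (1.77 to 3.38). Antibody transcripts were far lower, Igkc, the kappa light chain, at 2251 and 15 UMIs and Igha, the alpha heavy chain of IgA, at 273 and 0, at least 74.4-fold lower against 3 counts. Averaging over nuclei gave -5.91 for the log2 ratio of Igkc instead of -6.94, and thinning gave -4.59 for Igha instead of -6.22. In the whole PBS library 5 nuclei held 2488 of the 2752 Igkc UMIs.

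Astrocyte-like nuclei were higher in Hspb1, Gpx3 and Sult1a1 and lower in proteoglycan genes in the AEVs library. Hspb1, a small heat shock protein of reactive astrocytes, measured 640.4 CPM (615 to 667) in the PBS and 2437 CPM (2390.2 to 2484) in the AEVs library, 3.80-fold higher, Gpx3 had a log2 ratio of 2.75 (2.39 to 3.14), Sult1a1 2.94 (2.25 to 3.71) and Plin4, a coat protein of lipid droplets, 2.07 (1.32 to 2.89). Myoc, a secreted glycoprotein, was 6.26-fold lower, at 87.2 and 13.9 CPM, and Aplnr, the apelin receptor, had a log2 ratio of -1.57 (-1.96 to -1.18). Reactive astrocyte genes had 11 of 16 members higher, median 0.20 (0.12 to 0.31), with the iron-binding lipocalin Lcn2 at 1.05 and complement C3 at -0.68. Homeostatic genes had 9 of 14 lower, median -0.20 (-0.24 to -0.18) inside the middle 95% of random lists, with the water channel Aqp4 at -0.65 and the glutamate transporter Slc1a3 at 0.44. All 13 members of the chondroitin sulfate proteoglycan list, core proteins and enzymes of chain synthesis, were lower, median -0.33 (-0.46 to -0.22) at percentile 0.01, with aggrecan, Acan, at -1.22 (-2.65 to 0.09) and neurocan, Ncan, at -1.20 (-1.60 to -0.81). Oligodendrocyte precursor markers were lower with them for 7 of 8, median -0.45 (-0.52 to -0.34) at percentile 0.09. Vcan, Cspg4, Ptprz1 and Xylt1 are in both of these lists. Differentiating oligodendrocyte markers were lower for 4 of 4, median -0.57 (-0.80 to -0.40), while neuron markers had a median of 0.42 (0.21 to 0.70). Matrix genes had 8 of 18 higher and a median of -0.14 (-0.31 to 0.09). That median was 0.60 over members at 0.25 or more of the level of their highest class.

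In neuron-like nuclei Myl1, Ovgp1 and Rxfp2 were higher in the AEVs library, and most genes of the axon growth list were lower. Myl1, a myosin light chain of muscle, had 48 and 234 UMIs and a log2 ratio of 2.31 (1.86 to 2.79), Ovgp1, an oviductal glycoprotein, 1.83 (1.69 to 1.97), and Rxfp2, a relaxin family receptor, 1.82 (1.58 to 2.05). Hsph1, a heat shock chaperone, was lower, -1.29 (-1.39 to -1.19). Genes of axon growth and regeneration had 15 of 22 members lower, median -0.23 (-0.24 to -0.18) at percentile 0.01, with the neuropeptide galanin, Gal, at 1.01 (0.92 to 1.09), the growth cone protein Basp1 at 0.52, and Sprr1a, a gene of regenerating axons, at -0.81 (-0.96 to -0.66). Markers of other cells were lower in the same nuclei, with all 10 of oligodendrocytes at a median of -0.57 (-0.68 to -0.55), all 10 of astrocytes at -0.59 (-0.71 to -0.52) and all 8 of oligodendrocyte precursors at -0.47 (-0.53 to -0.33). Cluster 24 held 5.23% of the class in the PBS and 1.99% in the AEVs library. Axon guidance and growth inhibition genes had 16 of 23 lower, median -0.14 (-0.16 to -0.09), with the myelin-inhibitor receptor Rtn4r at 0.60 and the Slit receptor Robo1 at -0.54. Synapse genes had a median of -0.06 (-0.09 to -0.04), inside the middle 95% of random lists, with the vesicle protein Vamp2 at 0.48 and the adhesion protein Nlgn1 at -0.32. The median of all genes with at least 100 UMIs was 0.10 in this class.

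Fibroblast-like nuclei of the AEVs library were lower in matrix and early response genes. Of the matrix list 13 of 19 members were lower, median -0.76 (-0.88 to -0.56), with Postn, the scar protein periostin, at 318 and 29 UMIs and -2.56 (-3.16 to -2.01), Col1a1 at -1.95 (-2.05 to -1.84) and, in the other direction, Thbs1, thrombospondin-1, at 1.30 (1.07 to 1.53). The matrix metalloproteinases Mmp3 and Mmp13 were lower, Mmp3 with 177 and 3 UMIs and a log2 ratio of -4.99 (-7.28 to -3.42), Mmp13 with 122 and 2 UMIs and -5.04 (-8.10 to -3.15); averaging over nuclei gave -7.55 for Mmp3 and doublet calls kept -4.06, and thinning gave -3.00 for Mmp13. Nr4a3, an early response nuclear receptor, had 277 and 4 UMIs and a log2 ratio of -5.22 (-7.11 to -3.85), and Col14a1, a fibril-associated collagen, 335 and 13 UMIs and -3.79 (-4.72 to -3.00). Cxcl10, a chemokine of the pro-inflammatory list, was lower too, with -2.80 averaged over nuclei, -3.275 with doublet calls kept and -1.89 after thinning. Galnt15, a glycosyltransferase, was higher at 3.38 (2.85 to 3.94) and Cdh13, the anchored cadherin T-cadherin, at 2.22 (1.90 to 2.54). Hif3a was higher at 2.59, or 1.77 after thinning. Cell cycle genes had 15 of 17 lower, median -1.69 (-2.33 to -1.15), with Top2a at 55 and 0 UMIs. The median was -0.43 in the classes made without the genes named, -0.42 after thinning and -0.81 over members with at least 100 UMIs. The proteoglycan list had a median of 0.09, inside the middle 95% of random lists, and took the other sign under both other scalings. Cluster 8 held 77.4% of the class in the PBS and 54.1% in the AEVs library, 725 and 294 nuclei. Cluster 18 held the rest, 212 and 249 nuclei. Mural markers were higher for 6 of 7, median 0.77 (0.32 to 1.13), and oligodendrocyte markers lower for 8 of 10, median -0.40 (-0.52 to -0.25). TMM scaling would shift every value in this class by -0.13.

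Endothelial-like nuclei of the AEVs library were lower in early response genes. Apold1, an early response gene of vascular endothelium, had 277 and 29 UMIs and was 12.9-fold lower, and the transcription factors Fos and Egr1 had log2 ratios of -2.64 (-3.63 to -1.76) and -2.57 (-3.45 to -1.77), or -3.86 and -4.37 after thinning and -3.40 for Fos averaged over nuclei. All 15 measured members of the immediate early and heat shock list were lower, median -1.09 (-1.81 to -0.999). Angiogenesis genes had 11 of 14 lower, median -0.45 (-0.59 to -0.22), with the Notch ligand Dll4 at -2.33 (-3.78 to -1.09) and angiopoietin-1, Angpt1, at 1.00 (0.23 to 1.82), and barrier genes had 10 of 15 lower, median -0.27 (-0.37 to -0.09), with the lipid transporter Mfsd2a at -0.54 (-1.33 to 0.26). Cytl1, a secreted cytokine-like protein, was higher at 3.66 (2.58 to 5.01), or 2.69 averaged over nuclei and 2.89 after thinning, and Ccn2, connective tissue growth factor, at 2.45 (1.88 to 3.07). Cell cycle genes had 5 of 6 higher, median 0.54 (0.11 to 0.93) inside the middle 95% of random lists. The median was -0.30 over members with at least 1 UMI in each library. Mural markers had a median of 0.58 (0.12 to 0.77) in these nuclei, Schwann markers -0.77 (-1.44 to -0.40) and erythroid markers -1.35 (-1.58 to -1.21).

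Schwann-like nuclei carried more Apod in the AEVs library, 2026 and 7717 CPM, a log2 ratio of 1.93 (1.80 to 2.06), against 4520.1 and 24470.3 CPM in oligodendrocyte-like nuclei. Pink1, a kinase of mitochondrial quality control, was higher at 2.14 (1.28 to 3.10) and Deptor, an mTOR inhibitor, at 1.70 (1.00 to 2.45). With doublet calls kept the class held 87 PBS and 118 AEVs nuclei instead of 152 and 175, and the log2 ratio of Apod was 2.62 and that of Deptor 2.34. Pde10a, a cyclic nucleotide phosphodiesterase, was lower at -3.43 (-4.68 to -2.39) but -0.01 with doublet calls kept, -5.34 averaged over nuclei and -4.79 after thinning. Col14a1 was lower at -2.42 (-3.56 to -1.44). Oligodendrocyte precursor markers had a median of -1.08 (-1.45 to -0.57) and astrocyte markers 0.59 (0.17 to 1.06).

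Measures of RNA quality and handling differed between the libraries along with these genes. Mitochondrially encoded transcripts made up 0.374% of kept UMIs in the PBS and 0.235% in the AEVs library, and all 13 were lower over all nuclei, median -0.71 (-0.76 to -0.68), and in neuron-like nuclei, median -1.28 (-1.39 to -1.22). Their median was -0.66 in macrophage-like, -0.56 in astrocyte-like, -0.53 in microglia-like, -0.46 in endothelial-like, -0.39 in oligodendrocyte precursor-like and -0.39 in oligodendrocyte-like nuclei. It was -0.18 (-0.28 to -0.07) in fibroblast-like, -0.12 (-0.27 to -0.03) in Gpnmb-led myeloid and -0.06 (-0.15 to 0.11) in Schwann-like nuclei, all 3 inside the middle 95% of random lists. Immediate early and heat shock genes, which respond to handling of tissue, were lower for 17 of 18 members over all nuclei, median -0.56 (-0.66 to -0.49), with the early gene Fosb at -2.48 (-2.85 to -2.12) and the chaperone Hspa1b at -1.86 (-2.34 to -1.41). Their median was -0.90 (-1.16 to -0.78) in fibroblast-like, -0.60 (-0.82 to 0.11) in Schwann-like, -0.44 (-0.79 to -0.32) in astrocyte-like, -0.42 (-0.70 to -0.14) in oligodendrocyte precursor-like, -0.29 (-0.35 to -0.18) in neuron-like, -0.20 (-0.36 to 0.12) in oligodendrocyte-like, -0.20 (-0.40 to 0.05) in Gpnmb-led myeloid and -0.19 (-0.67 to 0.35) in macrophage-like nuclei, but 0.45 (0.18 to 0.76) in microglia-like nuclei. The Gpnmb-led myeloid and macrophage-like medians lay inside the middle 95% of random lists, and with doublet calls kept that of Schwann-like nuclei was 0.18. Erythroid markers were higher for 5 of 5 over all nuclei, median 1.08 (0.98 to 1.19). Their medians were 1.41 (1.05 to 1.55) in neuron-like, 0.94 (0.79 to 1.46) in oligodendrocyte-like and 1.14 (0.75 to 1.53) in astrocyte-like nuclei. In microglia-like nuclei the median was -0.22 (-0.63 to 0.28), inside the middle 95% of random lists. They were lower for 4 of 4 in fibroblast-like nuclei, median -0.24 (-0.58 to -0.07), and for 4 of 4 in endothelial-like nuclei, -1.35 (-1.58 to -1.21). Fibroblast markers were lower in several other classes too, with medians of -2.07 (-2.75 to -1.37) in microglia-like, -1.81 (-2.13 to -0.91) in oligodendrocyte-like, -1.61 (-2.43 to -0.74) in neuron-like, -1.32 (-1.69 to -1.02) in endothelial-like and -0.93 (-1.22 to -0.64) in Schwann-like nuclei, but -0.13 (-0.68 to 0.03) in astrocyte-like nuclei, at percentile 9.87. Sex-linked genes had a median of 0.12, inside the middle 95% of random lists, with the Y-linked Uty at 0.01 and Eif2s3y at 0.26 and with Xist, the X-inactivation RNA, at -0.70 (-0.998 to -0.40) from 254 and 152 UMIs.

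Over all nuclei, TMM scaling would shift every median given here by -0.10. Nuclear-encoded oxidative phosphorylation genes had 18 of 20 members higher, median 0.23 (0.20 to 0.25), with the complex I subunit Ndufb9 at 0.66 and Ppargc1a, a regulator of mitochondrial biogenesis, at -0.17. Oxidative stress genes had 16 of 21 higher, median 0.24 (0.18 to 0.31), with the quinone reductase Nqo1 at 1.26 (1.07 to 1.46) over all nuclei and 1.90 (1.55 to 2.27) in oligodendrocyte-like nuclei. Autophagy genes had 13 of 16 higher, median 0.12 (0.08 to 0.15), with the cargo receptor Sqstm1 at 0.51 and the lysosomal regulator Tfeb at -0.33. The oxidative phosphorylation and oxidative stress medians lay at percentiles 100 and 99.4, and the autophagy median at 89.4, inside the middle 95% of random lists. The cell cycle list had 19 of 24 lower, median -0.38 (-0.55 to -0.33), with Top2a at -2.003 (-2.40 to -1.62) and the checkpoint kinase Bub1b at 1.33 (1.04 to 1.64). Glycolysis, apoptosis, lipid handling, alternative activation, barrier and myelin genes had medians of 0.06, 0.02, 0.02, 0.03, 0.04 and 0.00, and each took the other sign under both other scalings and lay inside the middle 95% of random lists. Medians for the remaining lists were -0.10 for homeostatic and -0.19 for disease-associated microglia, -0.12 for pro-inflammatory, -0.14 for complement, 0.15 for reactive and -0.12 for homeostatic astrocyte, -0.25 for proteoglycan, -0.25 for differentiation, -0.27 for precursor, 0.39 for injured-oligodendrocyte, -0.03 for angiogenesis, -0.09 for axon growth, -0.18 for guidance and -0.05 for synapse genes. The same mix of clusters gave 0.09 for disease-associated microglia, and thinning gave 0.04 for synapse genes. The complement, reactive and homeostatic astrocyte, angiogenesis and synapse medians lay inside the middle 95% of random lists. Neurotrophic and growth factor genes had 13 of 20 lower, median -0.12 (-0.22 to -0.07), with the ciliary factor Cntf at 0.86 (0.67 to 1.05) and insulin-like growth factor Igf1 at -0.78 (-0.85 to -0.71).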

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

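The clock, cold-inducible, heat shock and glucocorticoid lists, the class that the free RNA ratio divides by, the rule by which depth was judged for the interferon list, the range used for mitochondrial RNA, and the tests that rest on 1 library per group were chosen only after the results were seen. Classes are compared with one another as differences between their list medians, and none of these differences was tested.

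Some lists went opposite ways in different classes. The cell cycle median was 0.54 in endothelial-like and -2.15 in oligodendrocyte precursor-like nuclei, 2.68 apart, but the endothelial-like value rests on 6 members and turned to -0.30 with members of 1 UMI or more in each library. Immediate early and heat shock genes stood at 0.45 in microglia-like and -1.09 in endothelial-like nuclei, 1.54 apart, and the immediate early genes alone at 0.63 and -1.79, 2.41 apart. Morning-phase clock genes stood at 0.49 in oligodendrocyte-like and -0.83 in fibroblast-like nuclei, 1.31 apart.

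Interferon response genes were higher in the AEVs library in several classes. Free RNA would add about as many interferon UMIs to each nucleus of every class. The gain per nucleus was 1.94 UMIs in microglia-like and 0.0775 in oligodendrocyte-like nuclei, the lowest gain above 0. Their ratio was 25.1 (23.2 to 27.0, from the microglia-like counts alone). This argues against free RNA for the microglia-like gain, and leaves gains as small as the oligodendrocyte-like one open. Schwann-like nuclei had a decrease, -0.240 (-0.460 to -0.017). Neuron-like, fibroblast-like and endothelial-like nuclei were left out of this comparison. Depth per nucleus was not settled. The microglia-like median in nuclei thinned to 1000 UMIs was 0.927 (0.713 to 1.08) of that at full depth. This lies above the 0.5 set beforehand for depth, although the interval reaches below the 0.8 set beforehand against it. Random thinning leaves the expected share of a gene within each nucleus as it was, whatever the depth did to it. It moves ratios through equal weights, nuclei left out and fewer counts. The value therefore cannot decide the question. With 1 library per group, the pool, the animals or the collection cannot be told apart from the treatment. A response to the vesicles themselves therefore stays open and untested.

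Cold-inducible genes, the RNA-binding protein genes Cirbp and Rbm3, were higher over all nuclei, median 1.499 (1.45 to 1.54), and heat shock genes lower, median -0.33 (-0.37 to -0.28), and these signs held in each class with a value. Time of day stays open, because evening and morning clock genes parted by over 0.5 in 1 direction in 3 classes, by -1.18 the other way in microglia-like nuclei, and by under 0.25 in 5 of 10, short of the 6 that would decide either way. Of those 3 classes, Schwann-like nuclei had only 4 evening and 2 morning genes measured, and macrophage-like nuclei 2 and 2. Cytoplasmic or mitochondrial RNA in nuclei stays open. Among nuclei with under 0.2% mitochondrial UMIs the difference was 0.880 of that in all nuclei as a median over 9 classes. This median met the 0.8 set beforehand against this explanation, but the range over classes was weighed too. Fibroblast-like nuclei, 106 PBS and 110 AEVs, were at 0.418, and endothelial-like nuclei, 20 PBS and 43 AEVs, at 0.394. Both fell under the 0.5 set beforehand for the median. Temperature or handling of the animals or tissue cannot be told apart from the treatment with 1 library per group. A treatment effect on these genes may exist but was not tested apart from these.

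High Cdkn1a, Apod and Hif3a in oligodendrocyte-like nuclei of the AEVs library was weighed as the pattern of the 5 genes with the highest ratios. Depth was not settled here either. Thinning leaves the expected share of a gene within each nucleus as it was, and the 5 genes were picked from these same counts. Their median log2 ratio in thinned nuclei was 1.05 (0.967 to 1.14) of that at full depth. A single cluster found mostly in the AEVs library is argued against, since outside cluster 5 the median was 2.61 (2.49 to 2.79), against 2.60 in the whole class. A systemic glucocorticoid state is a candidate explanation, as glucocorticoid-responsive genes had a median over 0.3 in 7 of 10 classes, among them 0.81 in oligodendrocyte-like nuclei. The median was 0.10 in neuron-like, 0.21 in oligodendrocyte precursor-like and 0.25 in endothelial-like nuclei. Within oligodendrocyte-like nuclei 7 of 10 members were higher and 3 lower, with Zbtb16 and Tsc22d3 the lowest. A glucocorticoid state and a direct effect of the vesicles both remain hypotheses, since the pool and the collection coincide with the treatment.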

How the results depend on the processing

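No paired analysis was possible because each group has 1 library. The same-mix alternative, the second clustering and, for lists, median-of-ratios factors, doublet calls kept and classes from genes scaled within each library, and resolution 2 for genes and lists of precursor-like nuclei, were chosen after seeing the data. Share ratios of fibroblast-like nuclei ranged from 0.505 to 0.54 over 7 alternatives, and of T or NK cell-like nuclei from 0.189 to 0.2 over 5, as the stricter nucleus filter and resolution 0.5 gave neither this class nor a macrophage-like one. With the filter of 800 genes and 1000 UMIs the share ratio of Gpnmb-led myeloid nuclei was 0.586, of microglia-like 1.232, of oligodendrocyte-like 1.022 and of Schwann-like nuclei 0.751, against 1.021. With doublet calls kept it was 0.613 for Gpnmb-led myeloid and 1.233 for neuron-like nuclei, with no mitochondrial limit 1.165 for microglia-like, and at resolution 2 0.916 for oligodendrocyte precursor-like nuclei, 112 PBS and 44 AEVs nuclei of that class being named differentiating oligodendrocyte-like there. Apart from the Schwann-like ratio, these stayed on their side of 1. The intervals of that ratio, of oligodendrocyte-like 1.022 (0.980 to 1.065) and of oligodendrocyte precursor-like 0.916 (0.785 to 1.07) include 1. With the same filter, so do those of astrocyte-like 1.08 (0.981 to 1.19), endothelial-like 1.20 (0.974 to 1.48) and oligodendrocyte precursor-like nuclei 0.881 (0.755 to 1.03). With no mitochondrial limit, astrocyte-like nuclei had 1.07 (0.986 to 1.17). Apart from the split at resolution 2, the cause was not tested.

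Among list medians, interferon genes in microglia-like nuclei ranged from 1.16 to 1.31 and injured-oligodendrocyte genes in oligodendrocyte-like nuclei from 0.62 to 0.78. Interferon genes in Gpnmb-led myeloid nuclei had 1.62 over members at 0.25 or more of their highest class. With members of at least 100 UMIs, oligodendrocyte precursor-like nuclei had 0.60 for interferon and -1.03 for cell cycle genes, since fewer and more abundant members were left, and at resolution 2 -2.61 for cell cycle genes. Matrix genes in fibroblast-like nuclei had -0.88 under TMM and -0.88 under median-of-ratios factors, as the class shift gives. Among values whose interval excluded 0, the sign reversed for disease-associated microglia genes over all nuclei with the same mix of clusters (0.09), synapse genes over all nuclei after thinning (0.039), glycolysis over all nuclei under TMM (-0.040) and median-of-ratios factors (-0.036), cell cycle genes in endothelial-like nuclei with members of 1 UMI or more in each library (-0.30), myelin genes (0.51) and Synpr (1.93, against -2.91) in oligodendrocyte precursor-like nuclei at resolution 2, and Fcgr2b in Schwann-like nuclei with doublet calls kept (0.26, against -1.79). Apart from the scalings and resolution 2, the cause was not tested.

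Of the values of named genes under all alternatives, 843 stayed within the counting interval, 121 left it without such a reversal and 2 reversed; of list medians 1444, 226 and 6. Thinning left out 1460 PBS and 1458 AEVs nuclei, and 46 of 120 values of named genes left their interval there, more than under any other alternative.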

Other observations

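The lists and genes in this part were chosen after their values were seen. Glucocorticoid-responsive genes, which adrenal steroids induce in most tissues, were higher in the AEVs library over all nuclei, with 8 of 10 members higher and a median log2 ratio of 0.46 (0.43 to 0.48). Arrdc2, an arrestin-domain protein, stood at 1.26 (1.14 to 1.37) and Pdk4, a kinase that restrains glucose oxidation, at 1.22 (1.07 to 1.37), while Zbtb16, a zinc finger transcription factor, was lower at -0.44 (-0.48 to -0.40). The median was 1.18 in macrophage-like, 0.99 in Schwann-like, 0.96 in microglia-like and 0.81 in oligodendrocyte-like nuclei, and 0.10 in neuron-like nuclei, where TMM scaling alone would shift it by -0.10. Cirbp and Rbm3, which rise when cells cool, measured 1.58 (1.51 to 1.65) and 1.42 (1.37 to 1.47) over all nuclei. Evening-phase clock genes had 8 of 8 members higher, median 0.35 (0.27 to 0.39), while morning-phase genes had a median of 0.06 (0.01 to 0.15) that the TMM shift of -0.10 over all nuclei would turn. Heat shock genes were lower in 16 of 16 cases over all nuclei, with medians of -0.64 in oligodendrocyte precursor-like, -0.45 in oligodendrocyte-like and -0.22 in neuron-like nuclei. Immediate early genes had medians of 0.63 (0.38 to 1.14) in microglia-like, 0.62 (0.31 to 0.81) in oligodendrocyte-like and -1.74 (-1.95 to -1.47) in fibroblast-like nuclei.

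Lymphocyte transcripts over whole libraries were fewer in the AEVs library, along with the number of T or NK cell-like nuclei. Cd3e, a chain of the T cell receptor complex, had 114 and 15 UMIs in the PBS and AEVs libraries, Themis, a regulator of T cell selection, 459 and 99, the chemokine Ccl5 592 and 158, and Gzmb, the cytotoxic protease granzyme B, 58 and 25. Some antibody genes were fewer too, Igkc with 2752 and 24 UMIs and Jchain, the joining chain of IgA and IgM, with 278 and 81, but Ighm, the heavy chain of IgM, had 889 and 990. Of the PBS UMIs of Jchain 181 came from 5 nuclei, and 323 of the 374 Igha UMIs of the PBS library came from 5 nuclei. For Gzmb, 5 nuclei held 33 of the 58 UMIs of PBS and 19 of the 25 of AEVs. Saa3 had 436 and 204 UMIs, the reverse of its direction in macrophage-like nuclei alone.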
